A study of Glycine max with 8 samples.

How the data were processed

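RNA was extracted from soybean nodules with Trizol, and libraries were made with a VAHTS Universal V6 kit for Illumina sequencing, per the labels' protocols. The labels give 8 libraries in 2 groups of 4: low nitrogen with Bra.Q2 (R), and low nitrogen with Bra.Q2 and Bac.B (BR). What the strain codes stand for beyond this was not used. Whether the kit was used in a stranded form is not given in the sources used here, so reads of overlapping genes cannot be told apart.

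The authors deposited a table of raw read counts per gene, with 1 column per library and no pooling. CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0 are named in the submitters' processing notes without their role or order. The genome build is not given in the sources used here, but the gene identifiers carry the annotation name Wm82.a2.v1, per the file headers and rows. The authors also deposited FPKM (fragments scaled to gene length and library total) for 39910 genes. Dividing the deposited counts by the FPKM and by each library's total gave a single gene length in all libraries for all 39910 genes, within 0.1%, so that the FPKM are the counts scaled by total and length with no further normalization. These lengths, from 152 to 16968 bases, were used as gene lengths. The 3607 genes absent from the FPKM table had 0 counts in all libraries. All rows of the count table name a gene, and 266 of them lie on unplaced scaffolds. HTSeq and similar counters differ in how they treat reads that fit several copies, so values of near-identical genes, which are frequent in soybean, are uncertain.

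The reference gene table describes assembly Glycine_max_v4.0 and holds none of the deposited identifiers: 0 of 43517 matched. Gene names were therefore not used, no coordinates are given, and the 33 gene lists that had been fixed before the data were examined, which rest on gene descriptions, could not be applied; neither could their tests. The chromosome of a gene and its order along it were read from the identifier, which by the naming scheme of this annotation carries the chromosome number and a serial number that increases along the chromosome. The rule for named genes took, among called genes with a mean of at least 1 CPM and no overlap between groups, those with the largest fold changes in each direction; it provided for 8 per direction and was limited to 2 because the sources used here hold no names for the identifiers.

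Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, which left 29508, libraries were scaled by TMM, and BR was compared with R by the quasi-likelihood F test without covariates. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p below 0.05 were called. Log2 fold changes are BR over R, and each SE is the fold change divided by the square root of its F statistic. Log2 CPM with a prior count of 2 were used for correlations, principal components and within-group variances. On simulated data for this comparison, with 29508 genes of which 200 were changed, 81% of the 4-fold and 16% of the 2-fold changes were called, and 7.6% of the calls were false. With so few changed genes the adjustment is stricter than in the real comparison. The simulation also drew genes independently and with the same dispersion in both groups, whereas the R libraries varied more than the BR libraries. These rates are therefore not those of the real calls.

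Library totals were 15133989, 17287964, 16587402 and 16624562 counts for BR1 to BR4 and 15266510, 14829669, 14223489 and 14674869 for R1 to R4. TMM factors were 1.05 to 1.10 in BR and 0.913 to 0.951 in R. The labels list 8 samples, and these were analysed as 8. The lowest chi-square per degree of freedom between any pair was 7.24 within BR and 12.5 within R, above counting noise, which does not show that they came from separate plants. Group means of per-library measures were compared with exact two-sided permutation tests, for which p = 0.0286 is the smallest possible value, and adjusted over the 13 measures. Many of these measures overlap, such as shares of a single total and gene detection before and after thinning. An adjusted p of 0.0465 in these tests is reached only because several measures tie at that smallest value. Where the depth could matter, libraries were thinned at random to 14223489 counts. Chromosomes were tested with Fisher's exact test and with camera of limma 3.58.1. Neighbours and runs of neighbours were tested by shuffling calls within chromosomes; the runs were also counted under the other scalings, chosen after seeing the data. The abundance classes, length classes, chromosome and neighbour comparisons were chosen after the files had been opened.

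The alternatives tried were DESeq2 1.42.0, limma-voom with and without library weights, RLE and upper-quartile factors, no filter and a stricter filter on low counts, a block on the replicate number, each library left out in turn, stricter thresholds, and limma on log2 of the deposited FPKM plus a pseudocount of 1 or 0.1. Added after seeing the data were scaling by total counts, removal of each library's length trend, thinning, and leaving out R1 and R2 or R3 and R4. The replicate numbers are shared between the groups, but nothing in the labels says that they pair plants, so the main test has no block.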

Results

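Nodules are the root organs in which soybean (Glycine max) and other legumes house nitrogen-fixing rhizobia. Nodule RNA was sequenced from plants kept at low nitrogen under 2 treatments. Plants of group R had received the strain labelled Bra.Q2 alone, and plants of group BR had received Bra.Q2 together with a second strain labelled Bac.B. Each group held 4 libraries, named here by group and replicate (BR1 to BR4 and R1 to R4). The counts covered 43517 soybean genes, of which 3607 had 0 counts in every library. Totals ranged from 15133989 to 17287964 counts in the BR libraries and from 14223489 to 15266510 in the R libraries. The design holds 1 comparison, BR against R, which asks how nodule transcript levels differed when the second strain was added. Nothing in the labels says whether libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical. The genes carry Wm82.a2.v1 identifiers that neither deposited file pairs with names, so changes are described by abundance, gene length, chromosome and position, and identifiers are given for 4 genes only.

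The BR libraries resembled each other more closely than the R libraries did. Correlations of log2 CPM (counts scaled to a common library total) across the 29508 tested genes lay between 0.955 and 0.981 within BR, between 0.903 and 0.975 within R, and between 0.889 and 0.937 across groups. The first principal component held 48.6% of the variance. All 4 BR libraries scored between -62.2 and -51.1 on it, whereas R2 scored -3.1, R1 29.1, R3 95.9 and R4 102.5 (difference of means -112 in an exact two-sided permutation test, p = 0.0286, the smallest that 4 libraries against 4 can give; adjusted p = 0.0465 over 13 library measures). The second component, with 22% of the variance, set R1 (-51.7) and R2 (-91.5) apart from the other libraries, which scored between 9.1 and 36.2. The median within-group variance of log2 CPM was 0.109 in R and 0.0661 in BR, a ratio of 1.65, and 64.3% of genes varied more among R than among BR libraries.

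**Figure D1:**
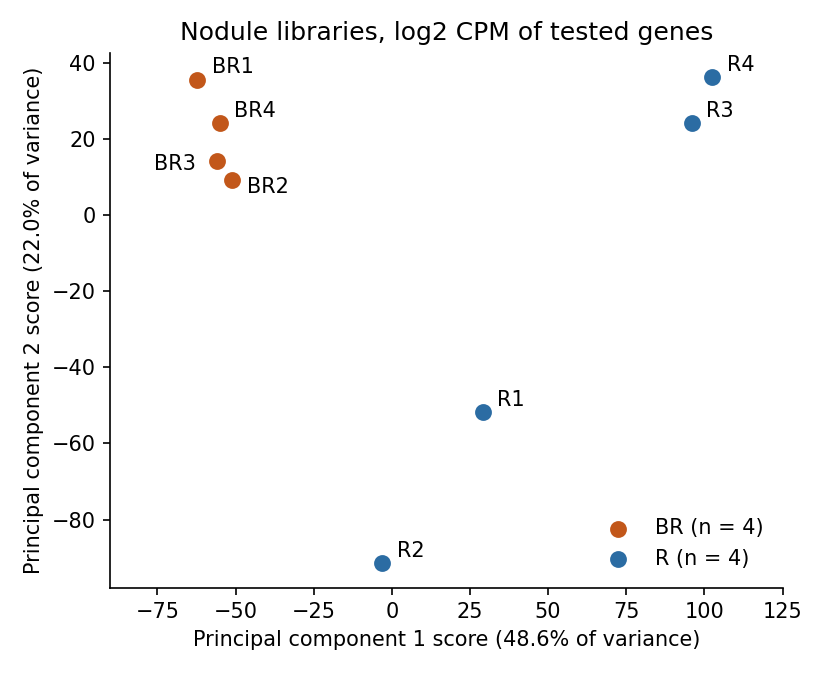
Scores of the 8 nodule libraries on the first and second principal components of log2 CPM over the tested genes; each point is 1 library, coloured by group. The BR libraries lie together at the left, between -62.2 and -51.1 on the first component, while the R libraries extend from -3.1 to 102.5.

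Adding Bac.B to Bra.Q2 was accompanied by a change in 5409 of the 29508 tested nodule genes, or 18.3%. In BR, 2355 genes were higher and 3054 were lower than in R (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Changes were mostly moderate, with a median of 1.96-fold among the called genes. At least a 2-fold change was seen in 1192 of the higher and 1360 of the lower genes, at least 4-fold in 233 and 280, and at least 8-fold in 35 and 50. In 4971 of the 5409 called genes, all 4 BR libraries lay on one side of all 4 R libraries. Over all tested genes 24.5% were separated in this way, against 2.86% expected by chance. No gene had 0 counts in every library of one group and 10 or more in every library of the other.

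The balance between higher and lower genes moved with the scaling. Relative to TMM, the scaling of the main test, upper-quartile scaling raised the median log2 fold change of all genes by 0.11 and scaling by total counts alone raised it by 0.19. The higher genes made up 43.5% of the calls with TMM, 57.7% with upper-quartile scaling and 71.2% with total counts. All 2355 higher genes and 1739 of the 3054 lower genes were called in the same direction under TMM, RLE, upper-quartile and total-count scaling; a shift of all genes upward favours keeping the higher calls. The number of calls also changed when single libraries were left out. It fell to 3494 without BR1, 4375 without BR2, 2848 without BR3 and 2868 without BR4. It fell to 3961 without R1, 3535 without R3 and 3392 without R4, but rose to 7333 without R2. Fewer libraries give less power, so a fall alone does not single out a library. With R3 and R4 both left out 3554 genes were called, and with R1 and R2 both left out 10237 were called.

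**Figure D2:**
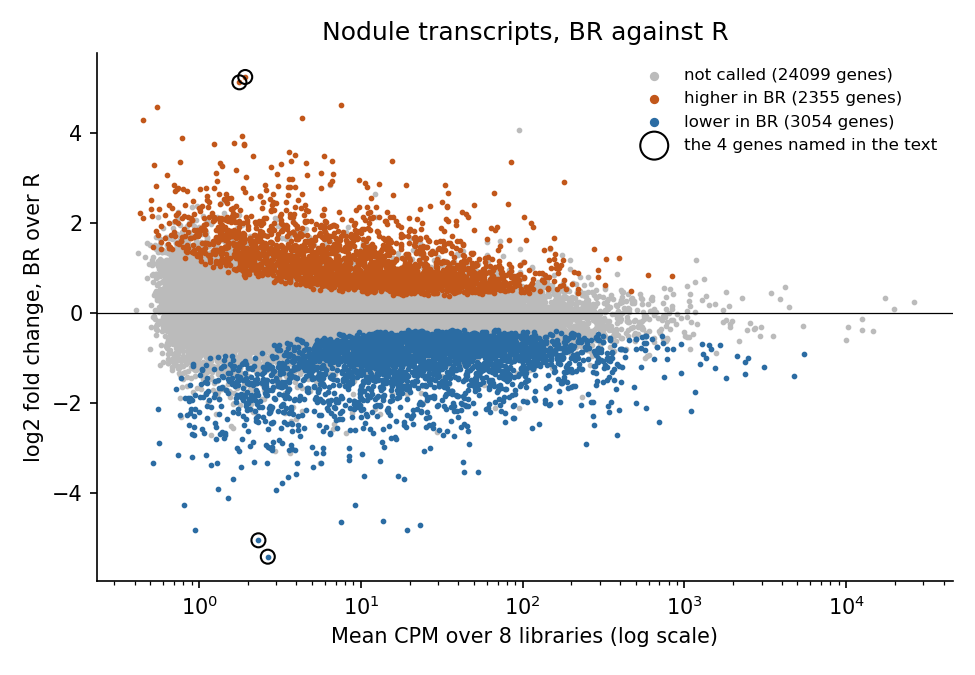
Log2 fold change (BR over R, TMM scaling) of each tested gene against its mean CPM over the 8 libraries, on a log axis; colours mark the 2355 genes higher and the 3054 genes lower in BR, and open circles the 4 genes named in the text. Among genes of high abundance, lower calls outnumber higher calls.

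The strongest changes were in transcripts that were nearly absent from one group. Glyma.20G098900.Wm82.a2.v1, on chromosome 20, rose from 0.0911 ± 0.0915 CPM in R to 3.77 ± 1.85 CPM in BR (SD, n = 4), a log2 fold change of 5.25 (SE 0.65; edgeR adjusted p = 0.00178). Its counts were 41, 33, 101 and 91 in BR1 to BR4 and 0, 1, 1 and 3 in R1 to R4. Glyma.12G094400.Wm82.a2.v1, on chromosome 12, rose from 0.0904 ± 0.137 to 3.46 ± 1.55 CPM, by 5.14 on the log2 scale (SE 0.71; edgeR adjusted p = 0.0026). In the other direction, Glyma.01G005100.Wm82.a2.v1, on chromosome 1, had 5.21 ± 4 CPM in R and 0.11 ± 0.184 CPM in BR, a log2 fold change of -5.43 (SE 0.9; edgeR adjusted p = 0.0051). Glyma.06G006500.Wm82.a2.v1, on chromosome 6, had 4.53 ± 2.17 CPM in R and 0.126 ± 0.0801 CPM in BR, a log2 fold change of -5.06 (SE 0.54; edgeR adjusted p = 0.00105). All 4 genes separated the groups without overlap, which the rule for naming them required. With so few reads in the lower group, the size of each fold change depends on the prior count of the fit and on single libraries; the log2 fold change of the chromosome 1 gene was -7.57 without BR2, and that of the chromosome 12 gene 6.76 without R2.

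No difference between treatments passed the test for the most abundant nodule transcripts. The 8 genes with the most reads took 12.9% ± 1.06 of the counts in BR and 11.7% ± 1.93 in R (SD, n = 4; exact two-sided permutation test, p = 0.371). None of the 8 was called under any of the 4 scalings; their log2 fold changes lay between -0.59 and 0.32, and the lowest edgeR adjusted p was 0.0502 with TMM. The single most abundant gene took 3.03% ± 0.562 of the counts in BR and 2.22% ± 0.523 in R; its TMM-scaled log2 fold change was 0.25 (SE 0.25; edgeR adjusted p = 0.506).

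Over the whole range, the direction of change followed abundance. Among the 1531 genes with a mean above 100 CPM, 386 fell in BR and 64 rose, so that 14.2% of the calls were higher. Among the 7044 genes between 20 and 100 CPM, 1239 fell and 598 rose. Among the 8493 genes between 1 and 5 CPM, 718 rose and 372 fell, and among the 1624 genes below 1 CPM, 82 rose and 29 fell, or 73.9% higher. With total-count scaling the higher share of the calls also declined from class to class, from 88.1% below 1 CPM to 36.7% above 100 CPM, but the classes from 5 to 20 CPM and from 20 to 100 CPM then held more higher than lower genes. With upper-quartile scaling this was so only for the class from 5 to 20 CPM. As shares of the tested reads, which amount to total-count scaling, genes above 100 CPM took 55.3% ± 0.256 in BR and 57.7% ± 1.67 in R, genes from 5 to 20 CPM 12.45% ± 0.214 and 11.22% ± 0.447, genes from 1 to 5 CPM 2.55% ± 0.115 and 2.04% ± 0.175, and genes below 1 CPM 0.151% ± 0.0116 and 0.109% ± 0.0182 (SD, n = 4; for each, exact two-sided permutation p = 0.0286 and adjusted p = 0.0465 over 13 measures). Genes from 20 to 100 CPM took 29.59% ± 0.324 and 28.9% ± 1.3 (permutation p = 0.371, adjusted p = 0.402). These shares are parts of a single total, so their tests are not separate results. Their adjusted p of 0.0465 falls below 0.05 only because several overlapping measures tie at the smallest permutation p. The share above 100 CPM was not uniform within R. It was 59.8% in R1 and 58.2% in R2, but 56% in R3 and 56.9% in R4, against 55% to 55.5% in BR. The 100 genes with the most reads in each library took 27.28% ± 1.115 in BR and 27.7% ± 2.41 in R (exact two-sided permutation test, p = 0.771).

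Called genes were more often higher in BR among short genes than among longer ones. Of the 3085 tested genes of up to 1000 bases, 465 were higher and 195 lower in BR, so that 70.5% of the calls were higher. Of the 26423 longer genes, 1890 were higher and 2859 lower, or 39.8% higher. Under total-count scaling these shares were 85.3% and 68.6%, and under upper-quartile scaling 78.8% and 54.4%, so the direction of the longer genes as a set depended on the scaling, and the gap between short and longer genes went from 30.7 percentage points with TMM to 24.4 with upper-quartile scaling and 16.6 with total counts. It was 12.1 points without R3 and R4, and 7.97 with each library's length trend removed. Over all tested genes, the Spearman correlation of gene length with the fold change was -0.125, a value across genes, which are not independent replicates. The trend was not uniform within the groups. The slope of log2 CPM on log2 length, relative to the mean of the 8 libraries, was -0.148 in BR1, 0.0142 in BR2, -0.0103 in BR3 and -0.0659 in BR4. It was -0.0447 in R1, -0.0357 in R2, 0.142 in R3 and 0.148 in R4. The group means of -0.0525 ± 0.072 and 0.0524 ± 0.107 (SD, n = 4) did not pass the test against the spread between libraries (exact two-sided permutation test, p = 0.229), and without R3 and R4 the difference of -0.105 became -0.0186.

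**Figure D3:**
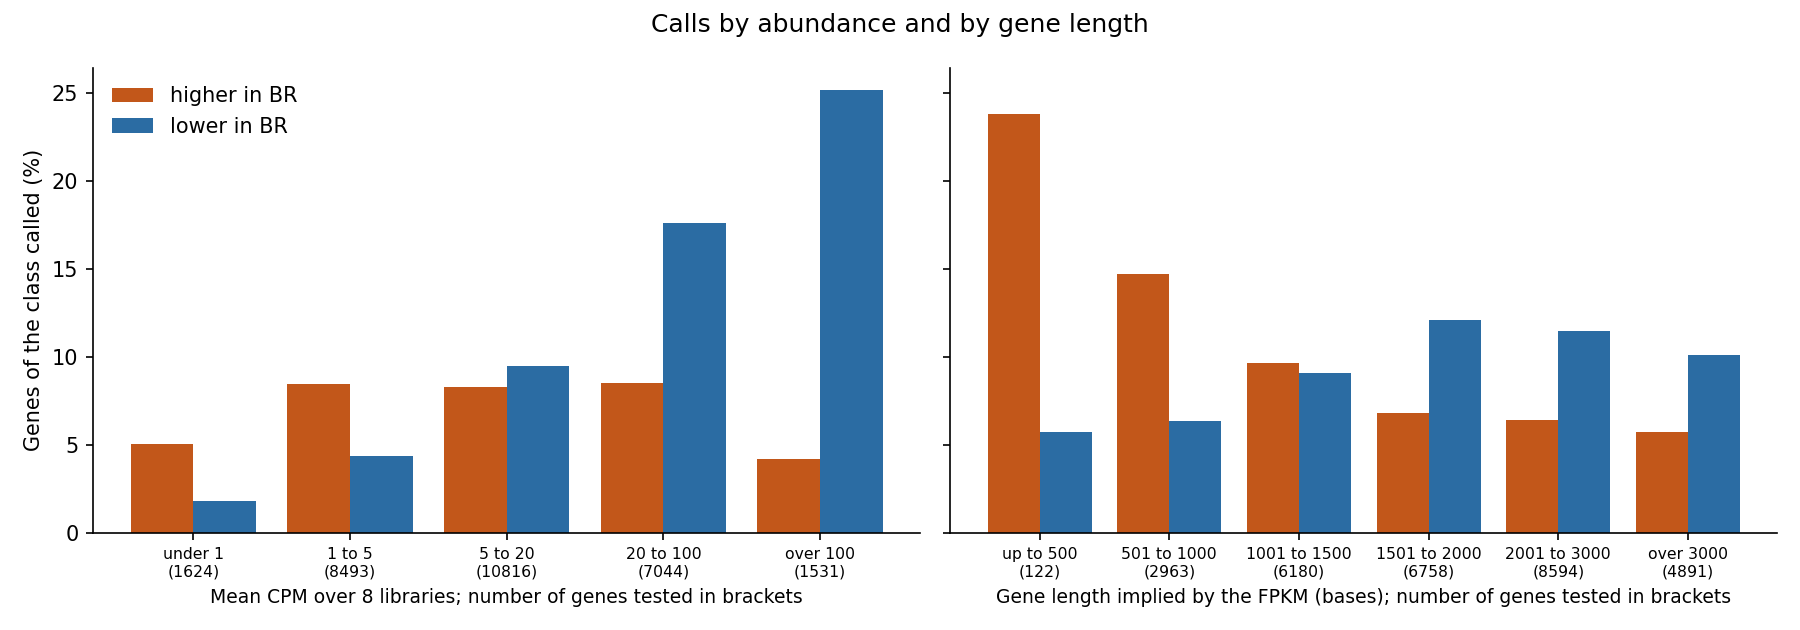
Percentage of tested genes called higher or lower in BR (edgeR, TMM scaling), by mean CPM over the 8 libraries (left) and by gene length in bases (right); the number of tested genes in each class is in brackets. Above 100 CPM 25.2% of genes were lower and 4.18% higher, and from 501 to 1000 bases 14.7% were higher and 6.34% lower.

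**Figure D4:**
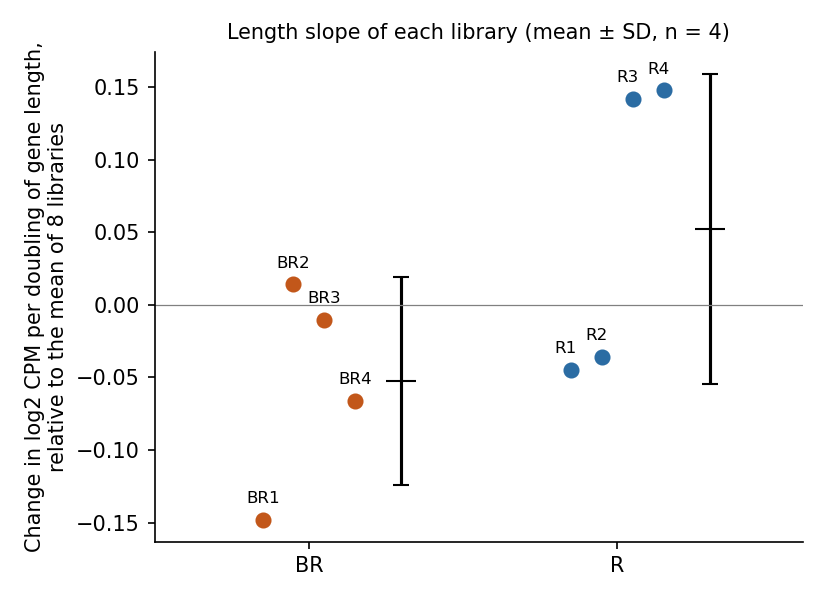
Change in log2 CPM per doubling of gene length in each library, relative to the mean of the 8 libraries; points are libraries and bars the group mean with its SD (n = 4). R3 and R4, at 0.142 and 0.148, stand above R1 and R2, which lie among the BR libraries.

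Called genes lay on all 20 chromosomes. The share of tested genes that were called ranged from 16.6% on chromosome 16 to 20.1% on chromosome 13. No chromosome passed a test of its share of called genes against the rest (Fisher's exact test, lowest adjusted p = 0.678 over 21 sets, the 20 chromosomes and the unplaced scaffolds); chromosome 13 alone had an unadjusted p below 0.05, at 0.0363. No set passed a test of movement in one direction relative to the other genes either. In limma's camera test 0 of the 21 passed and 0 had an unadjusted p below 0.05, with a lowest unadjusted p of 0.322 at the preset correlation of 0.01 and of 0.0615 with an estimated correlation, both on chromosome 5. On sets as large as whole chromosomes, the preset correlation makes this test insensitive to small shifts, so such shifts are not excluded.

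On a finer scale, adjacent genes were called in the same direction more often than shuffled calls were. The shuffles take genes as the units, so their p-values do not measure the spread between libraries. Among tested genes adjacent in identifier order on a chromosome, 628 pairs were called in the same direction, 1.25 times the 501.9 expected when calls were shuffled within chromosomes (permutation test with 10000 shuffles, one-sided p = 0.0001, the smallest these shuffles can give). Pairs called in opposite directions numbered 410, or 0.85 times the expectation (one-sided permutation p = 0.0002). The excess of same-direction pairs was 1.08 times at 2 places apart (permutation p = 0.0222) and 1.045 times at 3 to 5 places (p = 0.0265), and at 6 to 10 places it was 1.015 times (p = 0.208), which did not pass. Runs of 3 or more adjacent called genes of the same direction occurred 81 times, against 42.9 expected in 1000 shuffles (one-sided permutation p = 0.000999, the smallest these can give). With TMM 23 of them were higher and 58 lower in BR, and with total counts 84 were higher and 15 lower; the 84 did not pass against 76.9 expected (permutation p = 0.207), while the 15 stood against 5.81 (permutation p = 0.000999). The longest comprised 6 genes on chromosome 12, all lower in BR with log2 fold changes from -2.31 to -0.75. A run of 5 genes on chromosome 2 was lower by a mean log2 fold change of -1.64, and another of 5 genes on chromosome 17 by -1.

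**Figure D5:**
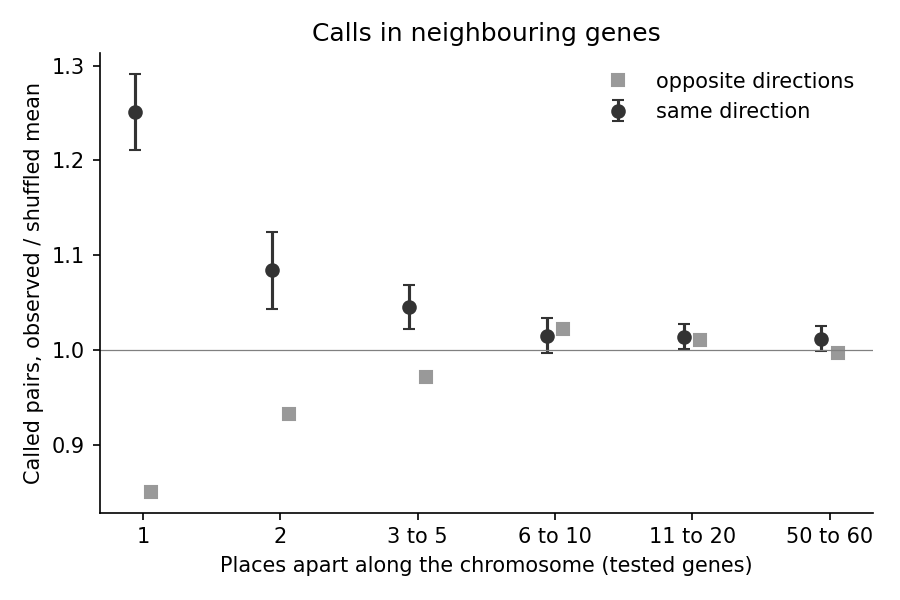
Number of gene pairs called in the same direction (circles) or in opposite directions (squares), divided by the mean number after shuffling calls within chromosomes, by distance in tested genes; bars are the SD of the same-direction count over shuffles divided by their mean. The same-direction ratio falls from 1.25 for adjacent genes to near 1 beyond 5 places.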

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

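Each group of 4 libraries was searched for a library far from the others, over the library measures and the 4 named genes, 38 groups in all; chance flags about 1 in 20. Only Glyma.01G005100.Wm82.a2.v1, a gene lower in BR, gave such a library: BR2 had 0.382 CPM (7 counts), where BR1 and BR3 had 0 counts and BR4 had 1. All 4 BR libraries were below the lowest R library, at 1.65 CPM, as the rule for naming the gene required.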

How the results depend on the processing

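The tests with total counts, length trends removed, thinning and 2 R libraries left out were chosen after seeing the data. The gene list tests and their alternatives were not run, since none of the sources used here pairs the identifiers with descriptions. Leaving out 1 library gave 2848 to 7333 calls, 1282 to 3463 of them higher and 1539 to 3870 lower; fewest without BR3 and most without R2. Asking for at least 2-fold as well left 2552 (1192 higher, 1360 lower), and an adjusted p below 0.01 left 1540 (645 and 895). The FPKM tests called 4692 higher and 1691 lower genes with a pseudocount of 1, 4586 and 1682 with 0.1, and 4314 and 1664 above a mean FPKM of 1. These lie near scaling by total counts (4291 and 1739), because FPKM carry no composition factor. Without R3 and R4, 3554 were called, 1903 of them lower; without R1 and R2, 10237 (5160 higher, 5077 lower); fewer libraries enter both, and the cause of the rise was not tested. The remaining settings for the total count stayed within 1.5 times of 5409, including DESeq2 with 7204 calls, which held 5408 of the 5409. The replicate block gave 4633 calls, 4140 of them shared with the main fit. Deviations of same-numbered libraries correlated at 0.07, 0.09, -0.08 and 0.09. These values show no strong shared deviation, but they cannot tell whether the numbers mark pairs or blocks. The 4 named genes kept their direction and passed in 25 of 25 settings, with adjusted p-values up to 0.0206. They had been chosen for large folds and no overlap in these same libraries, which made this outcome likely. Their folds moved: without 1 library the log2 fold change on chromosome 20 was 4.88 to 6.09, on chromosome 12 4.75 to 6.76, on chromosome 1 -7.57 to -4.77 and on chromosome 6 -5.45 to -4.77. With FPKM and a pseudocount of 1 the log2 fold changes were 1.79, 1.54, -1.58 and -2.61. The neighbour ratio lay between 1.18 and 1.64 in 25 settings and passed in each. The higher share of the calls was 30.7 percentage points larger in genes up to 1000 bases than in longer ones; it was 12.1 points without R3 and R4, 24.4 with upper-quartile scaling, 16.6 with total counts, 15.4 to 17.1 with FPKM and 7.97 with length trends removed. The length slope difference did not pass in the 11 settings with at least 3 libraries per group (p from 0.143 to 0.4); with 2 R libraries the exact test cannot pass, and the differences were -0.0186 and -0.196. Below 1 CPM 111 of 1624 genes were called; how far depth limits calls in each class was not compared.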

Other observations

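More genes were detected in the BR libraries. At least 1 count was found for 36420 ± 427 genes in BR and 35230 ± 271 in R (SD, n = 4), and after thinning every library to the same total for 36190 ± 386 and 35170 ± 271, with no overlap between the groups (exact two-sided permutation test, p = 0.0286; adjusted p = 0.0465 over 13 measures). Of the 147 tested genes on unplaced scaffolds, 13 were higher and 19 lower in BR (Fisher's exact test of the share called, adjusted p = 0.795).

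When each library was held out and placed along the BR-R difference called from the other 7, with 0 at the mean of the opposite group and 1 at the mean of its own, BR1 to BR4 lay at 1.01, 0.79, 0.93 and 0.93, and R1 to R4 at 0.82, 0.57, 1 and 0.97. In R2, 57.3% of 7187 such genes were nearer the R mean than the BR mean, compared with 79% to 96.2% in the other libraries. Library weights estimated by voom were lowest for R2 (0.579) and highest for BR3 (2.67).

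The patterns below were noticed in these data; the tests of each were fixed before their own results were seen. For the count of changed genes, 1 of the 35 splits of the 8 libraries into 4 and 4, the real split with 5409 calls, gave as many; the highest of the other splits gave 0. Chance assignment of libraries is argued against as the source of the count, as far as 35 splits allow.

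The first pattern is the wider spread of the R libraries, 1.65 times the BR variance, with R1 and R2 apart from R3 and R4. A difference in depth is argued against, since the ratio was 1.61 after thinning to equal totals. Length bias that differs between libraries is argued against as the main source, since the ratio was 1.71 with each library's length trend removed. A BR library carrying an R label is argued against by R2, the most BR-like, which lay at 0.57, whereas a BR library would be near 0 with the scatter of the BR libraries (SD 0.091, n = 4), and which scored -91.5 on the second principal component, against 9.1 to 36.2 in BR; a mixed sample is not excluded, since 0.57 is also short of 1. The labels give no difference among R plants, harvests or batches, so no biological explanation of the spread was tested, and the intermediate position of R2 and an unrecorded batch remain open.

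The second pattern is the excess of higher calls among short genes. A length bias of whole libraries, as RNA integrity or fragment selection could produce, may contribute: the slope of the fold change on log2 length had the same sign in every abundance class, from -0.0226 (SE 0.034) below 1 CPM to -0.207 (SE 0.02) above 100 CPM, and the slopes of single libraries split R1 and R2 from R3 and R4 rather than BR from R. The SEs of these class slopes come from 200 resamplings of genes and do not measure the spread between libraries. The rise of the slope with abundance was not tested against that spread. Taken as it stands, the rise is not what a bias acting on length alone would give. A change with the treatment in short or in long abundant transcripts therefore also stays open. The thinned libraries kept 0.994 of the difference between groups. Random thinning keeps each gene's expected share of its library, so a value near 1 could be foreseen and does not decide about depth. With length trends removed the gap in the higher share between short and longer genes fell from 30.7 to 7.97 percentage points, which this removal brings about whatever the cause of the trend, and 4914 of the 5409 calls were kept.

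The third pattern is the joint change of neighbours. Reads shared between adjacent similar copies could add to it, as the ratio was 1.565 among neighbours with lengths within 25% of each other. Among neighbours whose lengths differ by more, the ratio was 1.14 (permutation p = 0.0025), which argues against copies of like length as the whole cause. Length only stands in for sequence, which was not compared, so reads shared between copies of unlike length are not excluded. Likeness of neighbours in abundance and length is argued against by a ratio of 1.24 when calls were shuffled within classes of both (permutation p = 0.0005, the smallest 2000 shuffles can give). Overlapping neighbours cannot be excluded for adjacent genes, because strand is not known and the ratio at 2 to 5 places, 1.06 (permutation p = 0.003), is above 1 but too small to decide. No biological explanation of the remainder was tested, and tandem gene families were not identified here.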
